A study of Mus musculus with 14 samples.

How the data were processed

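RNA was measured by sequencing in B cells sorted from the peripheral blood of 7 mice. The sort took CD19+ cells and divided them by a fluorescent Tomato mark (Tom) that tamoxifen had switched on: per the sample labels, mice received 50 mg/kg and were time-stamped at postnatal day 10. Per the series description, Tom+ cells are of early-life origin and Tom- cells of adult-life origin. Of the 7 mice, 4 carried the Eµ-TCL-1 transgene (TCL-1tg: mice 86, 94, 95 and 97), a B cell transgene known to give a disease like chronic lymphocytic leukaemia, and 3 were wild-type controls (WT: mice 83, 85 and 98). Each mouse gave 1 Tom+ and 1 Tom- library, which makes 14 libraries in 4 groups. Age at bleeding, sex, disease stage and cell number per library are not given in the labels.

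RNA came from cells lysed after sorting, and the cDNA kit was SMART-Seq v4 for very small inputs, followed by Nextera XT tagmentation, per the labels. These protocols amplify cDNA without molecular identifiers. The intervals and detection floors given here therefore cover counting error only, since copies made by amplification are not independent molecules.

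The values used are raw counts of reads per gene, in the table the authors deposited. They are whole numbers from 0 that add up to different totals in each library, with no sign of scaling. The authors' processing entry names STAR and the mm10 genome build, with no version or role for either. The tool that counted reads, the gene annotation, the strand setting and any filter are not stated. The table holds 46078 Ensembl mouse genes, with 0 lines that name no gene and 0 columns of other series. Of these genes, 45143 (98.0%) have an entry in GENCODE M21, which gave the coordinates (mm10, also called GRCm38), gene types and exonic lengths. No gene of the table is a transgene, reporter or Cre construct. Total counts ran from 30735425 to 73437822 per library.

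Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Shares, exact tests and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. edgeR's filterByExpr on all 14 libraries and 4 groups kept 17505 genes, 270 of them among the 397 immunoglobulin genes of the table. Library sizes were scaled by TMM. The test was edgeR's quasi-likelihood F test (robust glmQLFit, glmQLFTest), with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and no minimum fold. Every adjusted p for a gene is from edgeR unless another tool is named. CPM are counts scaled by the TMM library size, and each ± is 1 SD between mice unless a standard error (SE) is named. In each comparison of groups, the fit held the libraries of those groups alone. The difference of the Tom effect between genotypes was fitted on all 14 libraries, with 1 spread per gene shared by the 4 groups.

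The Tom+ and Tom- libraries of a mouse come from the same animal. The labels give the mouse of each library, and the main test, fixed before the data were examined, has no term for it. The same test with the mouse as a block was run as an alternative, and its calls are given with each of these comparisons. The deviation of each library from its group mean correlated weakly across genes between the libraries of a mouse (0.157 in mouse 86, 0.136 in mouse 94, at most 0.0615 in the other 5). Xist and Y-linked genes matched between the libraries of each mouse, apart from 2.37 CPM of Xist in the Tom+ library of mouse 97.

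Before the data were examined, 33 gene lists were fixed for use in each comparison. They cover B cell states (B-1, follicular B-2, marginal zone, memory and age-associated, B lineage identity, plasma cell and secretory), signalling (B cell receptor, immediate early and NF-kB, type I interferon, Toll-like receptor), chronic lymphocytic leukaemia, antigen presentation and fetal and neonatal lymphopoiesis. Others cover cell cycle, ribosome biogenesis and Myc targets, glycolysis and hypoxia, cholesterol and fatty acid synthesis, homing and migration, apoptosis and epigenetic regulators. Markers of other cells a blood sort could hold formed 8 lists: T cell, NK cell, monocyte and macrophage, neutrophil, erythroid, platelet, dendritic cell and B cell progenitor. The last lists hold B-1 associated V segments, immunoglobulin constant regions, cytosolic ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes. Each list with at least 5 tested genes (all but the neutrophil markers, with 3) was tested with camera (limma), which compares its genes with all others, at a preset inter-gene correlation of 0.01. camera was run again with an estimated correlation. P values were adjusted over the lists within each comparison. A count of members "adjusted over the list alone" applies the adjustment to the members only.

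Genes named in the text follow a rule fixed before the data were examined. It takes, for each comparison, up to 10 genes higher and 10 lower with the largest absolute log2 fold change at adjusted p below 0.05. These need a mean of at least 10 CPM in the higher group and the same direction in every mouse, or no overlap between genotypes. The rule leaves out Ig V, D and J segments, unnamed gene models (Gm, Rik) and pseudogenes. In the difference of Tom effects the condition on mice was not applied. In each list described, it takes the 2 to 4 members with the smallest adjusted p, or the 2 with the highest mean count where none passed. It always takes Cd5, Spn, Bhlhe41, Zbtb32, Ctla4, Fcer2a, Cr2, Ighd, Ighm, Sell, Lef1, Mki67, Tcl1, Bcl2 and Myc, and the V segments most used in each library. Where a gene was at 0 in every library of a group, its fold is a lower bound against a floor of 3 counts per library. It bounds counts and not expression, since molecules lost before counting are not covered. Where a group held 1 to 3 counts in all, levels are given without a fold.

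Use of V segments was measured as the share of counts on the 185 Ighv segments, or on the 165 Igkv and Iglv segments, taken by the segment with most counts. Single-library shares carry a 95% Wilson interval. Differences were tested with exact 2-sided permutation tests: sign flips within mice for Tom+ against Tom-, and regrouping of mice for TCL-1tg against WT. These 15 tests form 1 family for adjustment. Reads of near-identical V segments can be counted on a neighbour, so the name of a segment is less certain than the share.

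Alternatives fixed before the data were examined were RLE and upper quartile scaling, DESeq2, limma-voom with quality weights, no low-count filter, a strict filter (5 CPM in 3 libraries), removal of Ig genes before scaling, a block by mouse, all 14 libraries in 1 fit, and leaving out each mouse in turn. For lists they were the estimated correlation and fry, and for V use the effective number of segments (the exponential of the Shannon entropy) and a stricter set of segments. After seeing the data, 3 alternatives were added: genes with a mean of at least 20 CPM, the Xist-expressing mice left out, and the Tom- library of mouse 86 left out, the last also for the gene lists between genotypes in Tom- cells.

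The test was tried on simulated counts with the same depths and with 1 spread per gene, estimated from the data and equal in all groups compared. With 100 genes changed by a log2 fold of 3, it recovered 83% in the Tom comparison of TCL-1tg mice and 32% in that of WT mice. The genotype comparisons recovered 33% in Tom+ and 89% in Tom- cells, and the difference of Tom effects 48%. At a log2 fold of 1 the recovery was 33%, 0%, 0%, 64% and 1% in that order, with between 0 and 5 false calls. The simulated counts had no wider spread or extra zeros in WT Tom+ libraries, and no link between genes or between libraries of a mouse. The false calls therefore do not show how the test behaves under these features of the real data. Replicate libraries differed far beyond counting error, with a chi-square per degree of freedom between 35.5 and 468 for pairs of the same group.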

Results

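Gene expression was measured by bulk RNA sequencing in peripheral blood B cells of 7 mice, each sampled as a Tom+ fraction (cells marked by tamoxifen on postnatal day 10, of early-life origin) and a Tom- fraction (unmarked cells, of adult-life origin). Of these mice, 4 carried the Eµ-TCL-1 transgene (TCL-1tg) and 3 were wild type (WT). The 14 libraries therefore form 4 groups: TCL-1tg Tom+ and TCL-1tg Tom- (n = 4 each), and WT Tom+ and WT Tom- (n = 3 each). Total counts of the TCL-1tg Tom+ libraries were 56800346 in mouse 86, 67533525 in mouse 94, 61120180 in mouse 95 and 58624969 in mouse 97. The TCL-1tg Tom- libraries held 56290374, 56650495, 42499637 and 61877307 counts in the same order. The WT Tom+ libraries of mice 83, 85 and 98 held 30735425, 39405862 and 33069292 counts, and their WT Tom- libraries 73437822, 46161850 and 59110178.

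The WT Tom+ libraries were less complex than the others. They detected 14499 ± 2124 genes (n = 3), against 19322 ± 797 in TCL-1tg Tom+, 21456 ± 3228 in TCL-1tg Tom- and 20412 ± 1583 in WT Tom- libraries. Of the 17505 genes tested, 28.5% ± 2.82 had no count in a WT Tom+ library, against 6.50% ± 1.29, 4.35% ± 2.17 and 4.86% ± 0.900 in the same order. Ribosomal protein genes took 3.65% ± 0.632 of counts in WT Tom+ and between 1.42% and 1.61% on average in the other groups. Mitochondrially encoded genes took similar shares, between 0.573% and 0.684% on average. Xist, the RNA of the inactive X chromosome, was found at 63.2 to 93.8 CPM in both libraries of TCL-1tg mice 94 and 95, and Y-linked genes in the other 5 mice, all 3 WT mice among them. Tcl1, the mouse gene, stayed between 0 and 7 counts per library, and the table has no gene for the human transgene.

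**Figure D1:**
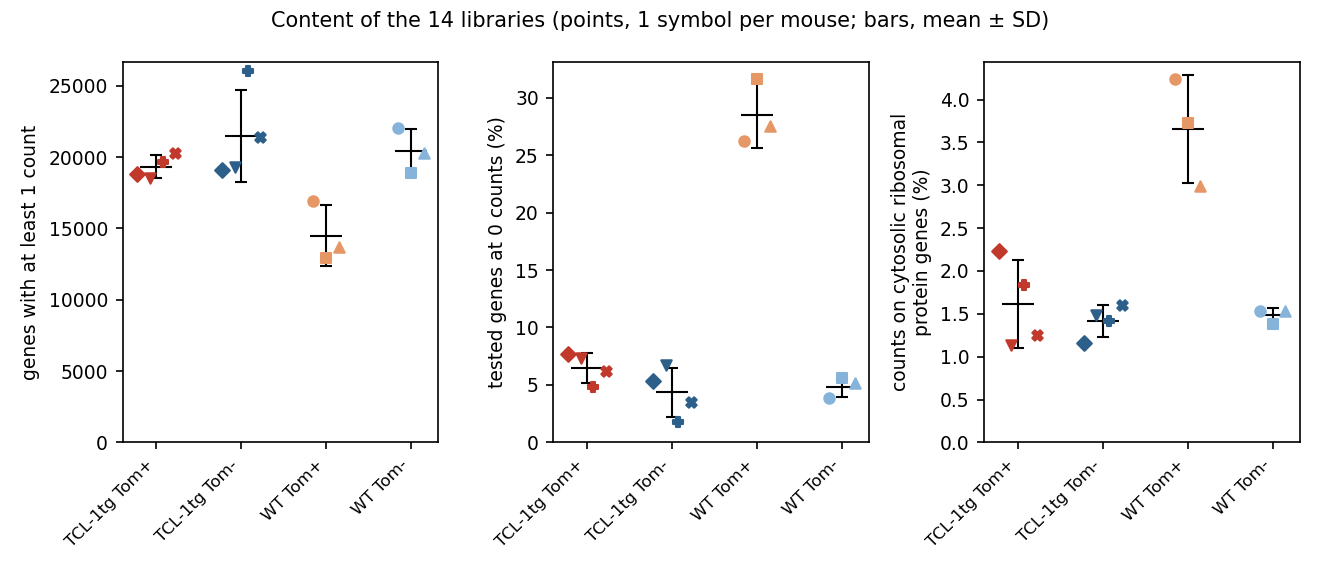
Genes detected per library, zeros among the tested genes (percent) and the ribosomal protein share of counts (percent), with 1 point per library and the mean ± SD of each of the 4 groups. The 3 WT Tom+ libraries lie between 26.2% and 31.7% zeros, above every other library.

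The use of antibody V segments bears on how far a B cell population is made of a few clones, and so on whether marked cells of leukaemia-prone mice are clonal. The shares are of reads from amplified cDNA and cell numbers are not given, so a library made from few cells could also show a leading segment. The WT Tom+ libraries, with 28.5% ± 2.82 of the tested genes at 0, had counts on 51 to 78 Ighv segments. TCL-1tg Tom+ libraries had counts on 59 to 79, and WT Tom- libraries on 130 or 131. In the Tom+ fraction of TCL-1tg mice, 1 heavy-chain segment took 79.5% ± 30.3 of all Ighv counts (n = 4), against 4.75% ± 0.162 in the Tom- fraction of the same mice. In WT mice the share was 39.1% ± 25.6 in Tom+ and 4.98% ± 0.284 in Tom- cells (n = 3). The segments of the Tom+ fraction differed between mice. Mouse 86 used Ighv12-3 for 93.6% of Ighv counts (95% Wilson interval 93.5 to 93.8), mouse 94 Ighv5-9-1 for 96.5% (96.5 to 96.6) and mouse 95 Ighv5-9 for 93.8% (93.7 to 93.9).

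Mouse 97 used Ighv11-2 for 34.2% of Ighv counts (33.8 to 34.5), Ighv7-1 for 29.7%, Ighv12-3 for 15.3% and Ighv6-6 for 8.57%. Among WT mice, Ighv11-2 led in mouse 83 with 17.1% (16.8 to 17.4) and in mouse 98 with 33.0% (32.6 to 33.4), and Ighv2-2 led in mouse 85 with 67.2% (66.7 to 67.6). Ighv11-2 and Ighv12-3 are segments known from B-1 cell antibodies that bind phosphatidylcholine. Ighv12-3 (ENSMUSG00000076676) lies on chromosome 12 at 114366521 to 114366954, Ighv11-2 (ENSMUSG00000096108) at 114048241 to 114048812. On the same chromosome lie Ighv5-9-1 at 113736111 to 113736630, Ighv5-9 at 113661769 to 113662293 and Ighv2-2 at 113588267 to 113588702, and all are annotated as V gene segments. In each Tom- library no heavy-chain segment passed 5.22%, and Ighv1-26 led in all but that of mouse 94, where Ighv5-17 led with 4.66%.

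The leading light-chain segment also took a larger share in Tom+ than in Tom- cells of each mouse. It took 68.3% ± 26.3 of Igkv and Iglv counts in TCL-1tg Tom+ and 14.7% ± 5.52 in TCL-1tg Tom- libraries (n = 4), and 35.8% ± 34.8 and 8.83% ± 0.218 in WT (n = 3). In TCL-1tg Tom+ cells it was Igkv4-91 in mouse 86 (93.4%, 93.3 to 93.5), Iglv2 in mouse 94 (78.3%, 78.2 to 78.5), Igkv6-17 in mouse 95 (69.9%, 69.6 to 70.1) and Igkv14-126 in mouse 97 (31.7%, 31.5 to 31.9). In WT Tom+ cells it was Igkv4-91 in mouse 83 (13.6%), Igkv12-98 in mouse 85 (75.9%, 75.8 to 76.1) and Iglv1 in mouse 98 (17.9%). Iglv1 led every Tom- library, with 22.8% in TCL-1tg mouse 86 and 8.58% to 13.3% in the other mice. The effective number of light-chain segments was 35.7 and 28.3 in the Tom+ libraries of WT mice 83 and 98.

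The heavy-chain share was higher in Tom+ than in Tom- cells in 7 of 7 mice, by 57.3 ± 33.9 points (exact sign-flip permutation test, 2-sided, p = 0.0156, the smallest this design allows, adjusted p = 0.117 over 15 tests). The light-chain share was higher by 42.2 ± 29.3 points in 7 of 7 mice (exact permutation p = 0.0156, adjusted p = 0.117). Within a genotype the design could not reach the threshold (smallest exact p = 0.125 for 4 TCL-1tg mice and 0.25 for 3 WT mice, and both were reached). TCL-1tg and WT Tom+ libraries differed by 40.5 points in the heavy-chain share (exact permutation p = 0.143, adjusted p = 0.268) and by 32.5 points in the light-chain share (exact p = 0.2). Neither passed with 4 and 3 mice. The effective number of segments differed by -18.3 for Ighv and -18.6 for light chains (TCL-1tg minus WT). Each gave an unadjusted exact permutation p of 0.0571, where 0.0286 is the smallest the design allows. All immunoglobulin genes together took 3.98% ± 1.31 and 3.09% ± 0.222 of counts in TCL-1tg Tom+ and Tom- cells, and 3.52% ± 0.0182 and 2.71% ± 0.0899 in WT. This share was higher in Tom+ cells in 6 of 7 mice, by 0.860 ± 0.884 points (exact permutation p = 0.0313, adjusted p = 0.156).

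**Figure D2:**
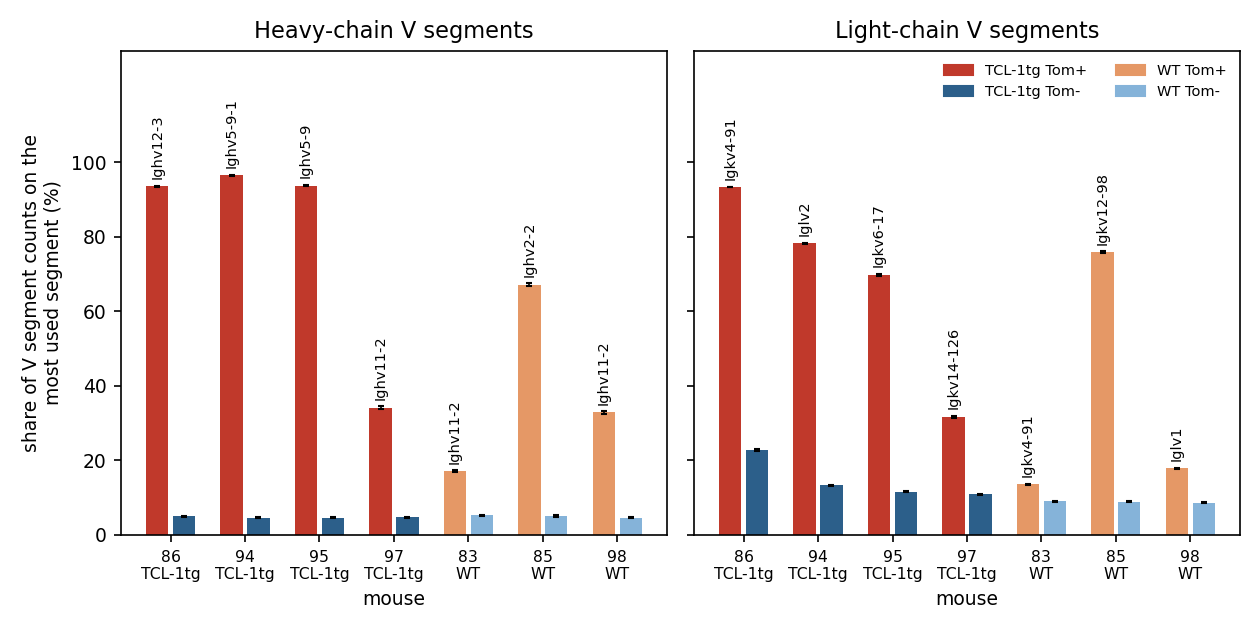
Share of Ighv counts, and of Igkv and Iglv counts, taken by the most used segment (percent, axis from 0) in the Tom+ and Tom- library of each mouse, with 95% Wilson intervals and the leading segment of each Tom+ library named. Heavy-chain shares of Tom+ libraries run from 17.1% to 96.5% and those of Tom- libraries from 4.61% to 5.22%.

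Comparing Tom+ with Tom- cells in TCL-1tg mice asks how B cells of early-life origin differ from those of adult-life origin in mice prone to a leukaemia-like disease. The Tom+ cells carried a B-1 cell profile: Zbtb32, a transcription repressor of B-1 and memory B cells, stood at 926 ± 175 CPM against 43.8 ± 41.4 (n = 4), 21.9-fold higher. Cd5, the classical surface marker of B-1a cells and of chronic lymphocytic leukaemia, stood at 42.9 ± 8.56 against 5.08 ± 2.62 CPM. Follicular B cell genes fell, among them Fcer2a, which encodes CD23, at 20.3 ± 18.0 against 947 ± 287 CPM and Cr2, which encodes the complement receptor CD21, at 10.7 ± 6.42 against 287 ± 113 CPM. Of 17505 genes, 1541 were higher and 1342 lower in Tom+ cells at an adjusted p below 0.05, 959 and 950 of them by at least 2-fold. Upper quartile scaling turned the balance, with 1350 higher and 1540 lower (46.7% higher, against 53.5%).

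Of 23 B-1 cell genes, 21 were higher and 1 lower (21 and 1 adjusted over the list alone), with a median log2 fold change of 3.15. camera gave an adjusted p of 8.41e-35 for the list, and 0.0138 with an estimated correlation. The lowest adjusted p were those of Ptpn22, a phosphatase of antigen receptor signalling (log2 fold change 3.09, SE 0.14, adjusted p = 9.70e-06), Pdcd1lg2, which encodes the ligand PD-L2 of B-1 cells (3.37, SE 0.16), S100a6 (4.06, SE 0.35) and Ahnak (2.66, SE 0.23). Bhlhe41, a transcription factor needed by B-1a cells, rose by 3.25 (SE 0.45), Ctla4 by 4.08 (SE 0.53) and Spn, which encodes CD43, by 1.79 (SE 0.30). The lower member was Bhlhe40 (-2.28), named after its values were seen. Zbtb32 (ENSMUSG00000006310) lies on chromosome 7 at 30589681 to 30598909 and Bhlhe41 (ENSMUSG00000030256) on chromosome 6 at 145858243 to 145865558. Cd5 (ENSMUSG00000024669) lies on chromosome 19 at 10717116 to 10739002, and Ctla4 (ENSMUSG00000026011) on chromosome 1 at 60887000 to 60915832.

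Of 16 follicular B-2 cell genes, 14 were lower and 0 higher (14 and 1 adjusted over the list alone), with a median of -1.83. camera gave an adjusted p of 3.01e-18, and adjusted p = 0.0885 with an estimated correlation. Satb1, a chromatin organiser of lymphocytes, was 190 ± 41.0 CPM in Tom- and 5.60 ± 2.15 in Tom+ cells, and Zfp318, which controls IgD splicing, was 168 ± 42.8 and 35.6 ± 10.9. Sell, the homing receptor CD62L, fell by 3.84 on the log2 scale (SE 0.46) and Il4ra by 1.06 (SE 0.14). Fcer2a (ENSMUSG00000005540) lies on chromosome 8 at 3681737 to 3694175, Cr2 (ENSMUSG00000026616) on chromosome 1 at 195136811 to 195176716 and Sell (ENSMUSG00000026581) on chromosome 1 at 164061982 to 164084181.

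Ighd, the IgD constant region, was 259 ± 110 CPM in Tom+ against 2652 ± 1051 in Tom- cells, and Ighm was 25412 ± 9346 against 14139 ± 2738. Ighg1 had no count in any Tom+ library and 27.1 ± 28.0 CPM in Tom- cells, at least 524-fold lower, and Ighg2b and Igha fell by 4.26 (SE 0.71) and 2.29 (SE 0.52). Among 12 constant regions, 1 was higher and 4 lower (2 and 5 adjusted over the list alone, median -1.02, camera adjusted p = 0.0394, and adjusted p = 0.340 with an estimated correlation). Of 257 tested Ig segments, 172 were lower and 5 higher. B-1 associated V segments went up and down: of 7, 4 were higher and 2 lower, with Ighv12-3 at 529 ± 864 CPM against 3.05 ± 0.559, Ighv11-2 at 124 ± 190 against 1.93 ± 0.553 and Igkv4-86 at 0.387 ± 0.380 against 6.96 ± 2.19 (camera adjusted p = 0.724). The Tom+ mean of Ighv12-3 rested largely on mouse 86 (98869 counts, others 1417 to 10506) and that of Ighv11-2 on mouse 97 (23422 counts, others 567 to 2286). Calls in this paragraph lost when a mouse was left out were Ighm (adjusted p = 0.117 without mouse 94, 0.167 without mouse 95), Ighg1 (0.0630, 0.0522 and 0.0632 without mouse 94, 95 or 97), Igha (0.0537 and 0.0707 without mouse 94 or 95) and Ighv11-2 (0.0628 without mouse 86).

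Growth genes rose in part. Myc stood at 397 ± 65.0 CPM in Tom+ and 67.3 ± 29.6 in Tom- cells (log2 fold change 2.61, SE 0.28). Of 22 ribosome biogenesis and Myc target genes, 7 were higher and 0 lower (13 and 0 adjusted over the list alone, median 0.49, camera adjusted p = 0.000177, and adjusted p = 0.692 with an estimated correlation). Srm, the spermidine synthase, rose 2.91-fold and Odc1, the first enzyme of polyamine synthesis, 2.11-fold. Of 31 cell cycle genes, 3 were higher and 1 lower (0 adjusted over the list alone, camera adjusted p = 0.864), and Mki67 was 15.7 ± 15.8 against 4.59 ± 2.07 CPM (adjusted p = 0.140). Bcl2, the survival gene, rose by 0.90 (SE 0.18). Of 19 genes tied to chronic lymphocytic leukaemia, 6 were higher and 2 lower (7 and 3 adjusted over the list alone), among them Il10 (4.81, SE 0.92) and Cd274, which encodes PD-L1 (1.38, SE 0.14), while Lef1 was 16.6 ± 17.0 against 16.7 ± 6.75 CPM. camera gave this list an adjusted p of 0.0534, and 0.0102 with the mouse as a block, and adjusted p = 0.539 with an estimated correlation and no block. Without mouse 95, Odc1 (adjusted p = 0.106) and Il10 (0.0616) lost their calls.

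**Figure D3:**
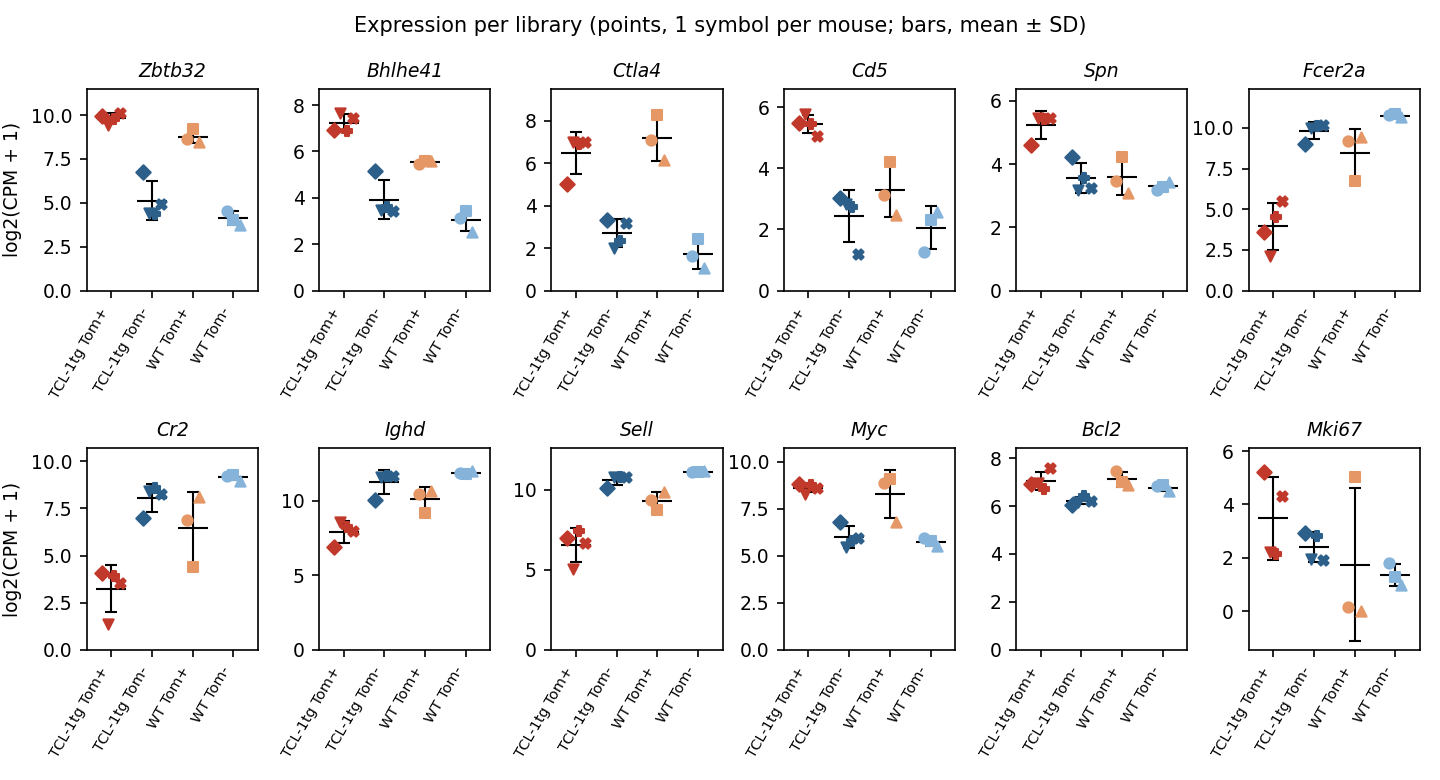
Expression of 12 named genes as log2(CPM + 1) in each of the 14 libraries, with 1 symbol per mouse, the mean ± SD of each group and 1 panel per gene. Zbtb32, Bhlhe41 and Cd5 are highest in TCL-1tg Tom+ libraries (mean 926, 152 and 42.9 CPM), and Fcer2a, Cr2, Ighd and Sell are lowest there (mean 20.3, 10.7, 259 and 108 CPM).

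The largest rises among genes of at least 10 CPM were Robo1 (43.2 ± 22.0 against 0.195 ± 0.173 CPM, log2 fold change 7.79, SE 0.87), a guidance receptor on chromosome 16 (ENSMUSG00000022883, 72308306 to 73046095), Tcerg1l (7.30), the transcription factor Prox1 (6.85) and the Wnt receptor Fzd6 (63.9 ± 15.3 against 0.680 ± 0.544 CPM, 6.58). Nrep (6.05), Klf5 (6.04), Acacb (64.0-fold), Sostdc1 (5.98), Gnb3 (568 ± 399 CPM, 5.95) and Kcnj5 (5.84) followed. The largest falls, after Ighg1, were Egfl6 (1 count over all Tom+ libraries, 10.6 ± 6.93 CPM in Tom- cells), Trim36 (-7.69), Zfp608 (0.295 ± 0.111 against 48.8 ± 7.44 CPM, -7.31) and Slc30a4 (-7.22). Next came Tle1 (-7.02), Tmem108 (-7.01), Emid1 (-6.87), Col27a1 (-6.64) and Sox4, a transcription factor of early B cells (0.361 ± 0.559 against 32.8 ± 13.6 CPM, -6.46). The naming rule required the same direction in each of the 4 mice, so the agreement of these genes between mice is not a separate result. Nrep (adjusted p = 0.0655), Acacb (0.0537) and Gnb3 (0.103) lost their calls without mouse 95, as Gnb3 did without mouse 97 (0.116).

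Markers of NK cells, monocytes and platelets were lower as lists in the Tom+ fraction. Summed NK cell markers were 5.98 ± 3.47 CPM in Tom+ and 46.7 ± 19.1 in Tom- cells (5 of 11 lower, 10 adjusted over the list alone, camera adjusted p = 0.000208, and adjusted p = 0.340 with an estimated correlation). Monocyte and macrophage markers were 128 ± 37.2 and 385 ± 181 CPM (6 of 14 lower, camera adjusted p = 0.000177, and adjusted p = 0.376 with an estimated correlation), with Lyz2 at 15.4 ± 3.64 and 198 ± 100 CPM. Platelet markers were 29.9 ± 20.6 and 80.9 ± 28.7 CPM (1 of 12 lower, camera adjusted p = 0.0133, and adjusted p = 0.692 with an estimated correlation). T cell markers summed to 1140 ± 62.4 and 683 ± 103 CPM. Most of this was Cd2, which mouse B cells also express, at 1091 ± 47.4 and 569 ± 72.8 CPM, while Cd8a, Cd8b1 and Trbc1 fell and lost their calls without mouse 95 (adjusted p of 0.0739, 0.149 and 0.176; 1 of 17 higher, 3 lower, camera adjusted p = 0.0164 downward, and adjusted p = 0.692 with an estimated correlation). Erythroid markers were 2804 ± 2374 and 3958 ± 1587 CPM (camera adjusted p = 0.192, 0.0361 with the mouse as a block, and adjusted p = 0.907 with an estimated correlation and no block). Dendritic cell markers were 294 ± 24.6 and 297 ± 31.8 CPM (2 higher and 1 lower of 8, camera adjusted p = 0.386) and neutrophil markers 0.630 ± 0.345 and 6.20 ± 3.10 CPM (1 of 3 lower, too few for camera). B cell progenitor genes summed to 631 ± 179 and 1128 ± 301 CPM, with 5 of 10 lower (8 adjusted over the list alone, median -4.91, and -4.86 with genes at 0 set to their bound, camera adjusted p = 5.59e-07, and adjusted p = 0.196 with an estimated correlation), among them Ms4a4c (-5.83) and Vpreb3 (-4.90).

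With the mouse as a block, 1314 genes were higher and 1157 lower, and of the genes called without it 1209 and 1045 remained. Without mouse 95 the counts were 665 and 595, and without mouse 97 they were 1027 and 1061. Leaving out the Xist-expressing mice 94 and 95, so that 2 remained per group, gave 166 and 165.

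The same contrast in WT mice asks whether early-life B cells differ from adult-life ones without the transgene. Zbtb32 stood at 445 ± 120 CPM in Tom+ and 16.7 ± 5.04 in Tom- cells (n = 3, log2 fold change 4.73, SE 0.34), and Ahr, the aryl hydrocarbon receptor, at 79.5 ± 15.1 and 4.50 ± 1.16 CPM (4.14, SE 0.34). The chemokine receptor gene Ccr1 was 95.4 ± 16.0 against 2.95 ± 1.41 CPM and Lmna, which encodes lamin A, 524 ± 264 against 18.2 ± 5.36 CPM. In all, 67 genes were higher and 21 lower in Tom+ cells, and the smallest adjusted p was 0.0339. With the mouse as a block edgeR called 0 of them (2416 genes at an unadjusted p below 0.05, smallest adjusted p = 0.270), so every WT call named here rests on the test without the block, while DESeq2 and limma-voom called more genes.

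Of 23 B-1 cell genes, 8 were higher and 0 lower (16 and 1 adjusted over the list alone), with a median of 2.65. camera gave an adjusted p of 6.01e-14, and adjusted p = 0.173 with an estimated correlation. Besides Zbtb32 these were led by Cd9, a tetraspanin of B-1 and marginal zone cells (2.29, SE 0.21), Fcrl5 (4.12, SE 0.39) and Ptpn22 (2.65, SE 0.26). Of 16 follicular genes none passed over all genes, while 12 were lower adjusted over the list alone (median -1.42, camera adjusted p = 0.000463, and adjusted p = 0.265 with an estimated correlation). Ighd stood at 1190 ± 557 against 3773 ± 325 CPM (adjusted p = 0.0576) and Cd22 at 857 ± 154 against 1776 ± 33.3 CPM. Several genes that passed in TCL-1tg mice did not pass in WT mice: Ctla4 (log2 fold change 6.07, adjusted p = 0.0510), Bhlhe41 (2.63, 0.0510), Sell (-1.74, 0.0510), Myc (2.83, 0.0511), Fcer2a (-1.92, 0.127), Cr2 (-2.06, 0.196), Cd5 (1.53, 0.362) and Spn (0.41, 0.748). The test of the difference between genotypes passed for Fcer2a (adjusted p = 0.0453) and Sell (0.0418), though for neither with the mouse as a block (0.129 each), and not for Ctla4 (0.185), Bhlhe41 (0.639), Myc (0.857), Cr2 (0.145), Cd5 (0.306) or Spn (0.154).

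B-1 associated V segments were higher in WT Tom+ cells, with Ighv11-2 at 312 ± 198 against 3.31 ± 1.51 CPM and Igkv14-126 at 521 ± 341 against 12.6 ± 2.22 CPM (2 of 7 higher, 5 adjusted over the list alone, camera adjusted p = 0.000394, and adjusted p = 0.265 with an estimated correlation). Cytosolic ribosomal protein genes were higher as well: 18 of 85 passed over all genes and 80 adjusted over the list alone, all upward, with a median of 1.35 (camera adjusted p = 9.66e-55, and adjusted p = 0.173 with an estimated correlation). Rps25 was 559 ± 76.0 against 180 ± 17.2 CPM and Rpl11 237 ± 10.9 against 104 ± 1.98 CPM. Of 82 oxidative phosphorylation genes, 1 was higher (45 adjusted over the list alone, median 0.80, camera adjusted p = 2.82e-26, and adjusted p = 0.173 with an estimated correlation), Atp5g1 at 136 ± 10.4 against 58.4 ± 3.22 CPM. In this comparison Tom+ libraries had 28.5% ± 2.82 of the tested genes at 0 and Tom- libraries 4.86% ± 0.900.

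The other genes with the largest rises were Rap1gap, a regulator of Rap1 signalling on chromosome 4 (ENSMUSG00000041351, 137664726 to 137729861), at 65.2 ± 49.3 against 1.07 ± 0.110 CPM (5.93, SE 0.68), Tppp3 (5.74), Tmc3 (5.37), the peptide hormone gene Adm (5.24), S100a6 (5.02) and Plscr1 (4.50). Spns3, Zfp28 and Foxred2 had no count in any WT Tom+ library and were at least 345-fold, 306-fold and 289-fold lower there against the counting floor. These folds bound counts and not expression, since 28.5% ± 2.82 of the tested genes were at 0 in these libraries. Dhx35 had 1 count in WT Tom+ cells and 36.2 ± 4.92 CPM in Tom- cells. Eif2ak4, a sensor of amino acid shortage, fell by 3.49 (SE 0.40), and Ptk2b, Pitpnm1, Strbp, Il4i1 and Snx29 fell by 1.73, 1.65, 1.61, 1.54 and 1.53.

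Summed NK cell markers were 0.0205 ± 0.0355 CPM in WT Tom+ and 24.4 ± 3.13 in Tom- cells (0 of 11 passing over all genes, 8 lower adjusted over the list alone, camera adjusted p = 0.000148, and adjusted p = 0.173 with an estimated correlation). These markers were weak in WT Tom- cells, with Nkg7 at 8.15, Ccl5 at 4.48 and Gzma at 1.63 CPM. Weak genes lost to 0 in WT Tom+ libraries (28.5% ± 2.82 of tested genes at 0) cannot be told apart from fewer NK cells. Monocyte markers were 154 ± 91.7 and 280 ± 63.2 CPM (camera adjusted p = 0.00991, and adjusted p = 0.245 with an estimated correlation) and platelet markers 41.5 ± 33.6 and 66.6 ± 10.4 CPM (camera adjusted p = 0.0145, and adjusted p = 0.265 with an estimated correlation). B cell progenitor genes were 398 ± 67.1 and 788 ± 9.97 CPM (camera adjusted p = 0.00546, and adjusted p = 0.173 with an estimated correlation). T cell (846 ± 147 and 568 ± 91.8 CPM), erythroid (2353 ± 1752 and 2433 ± 2158 CPM) and dendritic cell markers (318 ± 52.3 and 268 ± 13.9 CPM) gave camera adjusted p of 0.0633, 0.854 and 0.517, and neutrophil markers were 2.98 ± 4.29 and 2.004 ± 0.836 CPM.

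Of the 67 genes higher in WT Tom+ cells, 43 were also higher in TCL-1tg Tom+ cells, where chance would give 5.90 (Fisher's exact test, p = 2.89e-29), and of the 21 lower, 12 were also lower (chance 1.61, Fisher's exact p = 6.02e-09). None of the 88 genes passed in the opposite direction in TCL-1tg mice. Across all 17505 genes the Tom effects of the genotypes correlated with Pearson r = 0.319 and Spearman rho = 0.328. Across the 7261 genes of at least 20 CPM, a minimum chosen after seeing the data, the values were 0.522 and 0.495. The effects share no library, though genes are not independent replicates. The WT calls rest on every library. Besides the test with the block, edgeR called 0 without mouse 83 (3888), without mouse 85 (3299) and without mouse 98 (4301). DESeq2 called 1537 higher and 2610 lower and limma-voom 391 and 773 on all libraries. The median log2 fold change of all genes was -0.32 with TMM, -0.28 with RLE and -0.18 with upper quartile scaling, which called 104 higher and 15 lower (87.4% higher, against 76.1%).

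**Figure D4:**
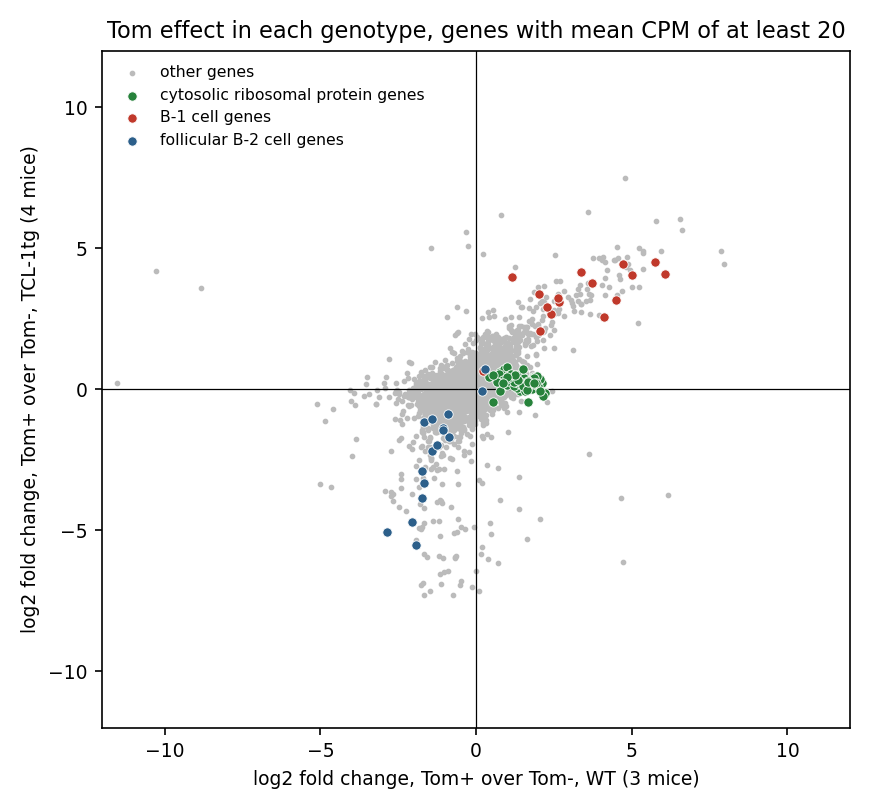
Log2 fold change of Tom+ over Tom- in TCL-1tg mice (vertical axis) against that in WT mice (horizontal axis) for 7259 genes with a mean of at least 20 CPM over the groups, with 16 B-1 cell, 16 follicular and 80 ribosomal protein genes coloured. B-1 cell genes lie mainly at the upper right (list medians 3.15 and 2.65), and ribosomal protein genes to the right of 0 (list medians 0.26 in TCL-1tg and 1.35 in WT).

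Comparing TCL-1tg with WT within the Tom+ fraction asks what the transgene changes in B cells of early-life origin. Nid1, which encodes the basement membrane protein nidogen and is a B-1 cell gene, stood at 727 ± 151 CPM in TCL-1tg (n = 4) and 93.6 ± 30.7 in WT cells (n = 3), 7.75-fold higher. Bhlhe41 stood at 152 ± 40.7 against 45.8 ± 2.52 CPM. Of the class-switched antibody transcripts, Ighg2b fell to 2.85 ± 1.74 against 183 ± 132 CPM and Igha to 39.6 ± 10.3 against 328 ± 171 CPM. Of all genes, 737 were higher and 122 lower in TCL-1tg, and 475 of the 737 had no count in any of the WT Tom+ libraries, which had 28.5% ± 2.82 of the tested genes at 0. The smallest adjusted p was 0.0367, so every call lay close to the threshold of 0.05.

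Among 23 B-1 cell genes, 4 were higher and 0 lower (8 adjusted over the list alone, median 0.85, camera adjusted p = 0.0594): Nid1, Bhlhe41, Cd9 (1.19, SE 0.25) and Itgam, which encodes CD11b. Cd5 stood at 42.9 ± 8.56 against 9.94 ± 6.69 CPM (adjusted p = 0.0581), Zbtb32 had a log2 fold change of 1.05 (0.0508), Spn of 1.68 (0.0684) and Ctla4 of -0.77 (0.477). Of 16 follicular genes, 3 were lower (8 adjusted over the list alone, median -1.02, camera adjusted p = 1.22e-06, and adjusted p = 0.542 with an estimated correlation): Sell (-2.61, SE 0.53), Ighd (-2.21, SE 0.47) and Fcer2a (-4.50, SE 0.96). Cr2 was 10.7 ± 6.42 against 138 ± 130 CPM (adjusted p = 0.0666). Among 12 constant regions, 3 were lower (1 higher and 3 lower adjusted over the list alone, median -1.58, camera adjusted p = 0.000753, and adjusted p = 0.542 with an estimated correlation), and 34 of 257 Ig segments were lower. Ighg2b (ENSMUSG00000076613) lies on chromosome 12 at 113302965 to 113307933 and Igha (ENSMUSG00000095079) at 113254830 to 113260236.

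Ribosomal protein genes were lower in TCL-1tg than in WT Tom+ cells, where the WT Tom+ libraries stood apart from all other groups in the ribosomal share of counts (3.65% against 1.42% to 1.61% on average) and in zeros (28.5% against 4.35% to 6.50%). Of these genes 28 of 85 were lower and 0 higher (69 and 0 adjusted over the list alone), with a median of -1.21 (camera adjusted p = 4.29e-40, and adjusted p = 0.542 with an estimated correlation). Rps27 was 155 ± 37.8 against 773 ± 285 CPM, Rps29 58.6 ± 22.3 against 314 ± 143 CPM and Rpl35 92.6 ± 32.8 against 310 ± 68.5 CPM. Of 82 oxidative phosphorylation genes, 1 was lower (0 adjusted over the list alone, median -0.57, camera adjusted p = 5.65e-15, and adjusted p = 0.663 with an estimated correlation), Cox7c at 30.5 ± 8.12 against 83.6 ± 17.6 CPM. Of 22 B cell receptor genes, 2 were higher and 0 lower (camera adjusted p = 0.851): Plcg2, a phospholipase of the receptor, at 714 ± 64.6 against 347 ± 90.8 CPM and Vav1 at 408 ± 50.5 against 241 ± 4.77 CPM. Prdm1, the regulator of plasma cell fate, rose by 1.36 (SE 0.26) and Creld2 by 1.19 (SE 0.18), while Cd40 fell by 1.24 (SE 0.22). Of the genes named for every comparison, Ighm (0.85), Mki67 (0.55), Myc (0.06) and Bcl2 (-0.06) did not pass. The WT level of Mki67 rested on mouse 85 (32.0 CPM, against 0.123 in mouse 83 and 0 in mouse 98).

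All genes with the largest rises had 0 or 1 count in WT Tom+ cells. Their lower bounds hold for counts and not for expression, since 28.5% ± 2.82 of the tested genes were at 0 in these libraries. Crmp1, on chromosome 5 (ENSMUSG00000029121, 37241940 to 37292133), at 33.4 ± 17.3 CPM was at least 399-fold higher, Pard6g 360-fold, Itgam 356-fold, Pik3r6, a regulatory subunit of phosphoinositide 3-kinase, 317-fold and Slc1a4 246-fold, each as a lower bound. Zfp28, Klf5, Sostdc1 and Hsd3b7 had lower bounds of 241-fold, 239-fold, 197-fold and 182-fold. Mcoln3 was 92.4 ± 75.8 CPM and Lef1, a Wnt pathway factor and marker of chronic lymphocytic leukaemia, 16.6 ± 17.0 CPM, each against 1 count in WT. Of the 19 leukaemia genes, Lef1 and Wnt10a were higher (4 adjusted over the list alone, median 2.86, and 1.35 with genes at 0 set to their bound, camera adjusted p = 0.0930). The largest falls after Ighg2b were Zfp608 (-5.81), Ms4a4c (3.37 ± 1.07 against 82.4 ± 54.8 CPM, -4.61), Fcer2a, Tiam2 (-4.48), Gadd45g (-3.62), Icosl (-3.50), BC094916 (-3.32), Arl4a (-3.17) and Pltp (-3.15).

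camera called no marker list of other cells, though single members passed. NK cell markers stood at 5.98 ± 3.47 against 0.0205 ± 0.0355 CPM (1 of 11 higher, camera adjusted p = 0.0829), monocyte markers at 128 ± 37.2 against 154 ± 91.7 CPM (2 of 14 higher, 1 lower, 0.250) and platelet markers at 29.9 ± 20.6 against 41.5 ± 33.6 CPM (2 of 12 higher, 0.323). T cell markers stood at 1140 ± 62.4 against 846 ± 147 CPM (1 of 17 higher, 0.280), erythroid markers at 2804 ± 2374 against 2353 ± 1752 CPM (0 of 11, 0.851) and dendritic cell markers at 294 ± 24.6 against 318 ± 52.3 CPM (2 of 8 higher, 0.0937). B cell progenitor genes stood at 631 ± 179 against 398 ± 67.1 CPM (1 of 10 higher, 1 lower, 0.851), and of 3 neutrophil markers none passed. The lower members were Ms4a6c (-2.48) among monocyte markers and Ms4a4c among progenitor genes. Every call here needs all TCL-1tg mice: edgeR called 0 genes without mouse 86 (3813 at an unadjusted p below 0.05), mouse 94 (3498), mouse 95 (3149) or mouse 97 (3484). It called 72 lower without mouse 83, and 1413 higher and 266 lower without mouse 98. DESeq2 called 2466 higher and 1201 lower and limma-voom 939 and 176 on all libraries. Limited to genes of at least 20 CPM the test called 10 higher and 11 lower, and the median of all genes was 0.30 with TMM, 0.26 with RLE and 0.14 with upper quartile scaling.

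Comparing TCL-1tg with WT within the Tom- fraction asks whether the transgene also changes B cells of adult-life origin. Only 3 of 17505 genes passed, all higher in TCL-1tg. Neto2, an accessory subunit of kainate receptors, stood at 145 ± 50.7 CPM in TCL-1tg (n = 4) and 0.911 ± 0.641 in WT cells (n = 3; log2 fold change 7.25, SE 0.51, adjusted p = 0.00257). Sufu, a suppressor of Hedgehog signalling, was 147 ± 4.95 against 83.1 ± 5.06 CPM (0.81, SE 0.08, adjusted p = 0.0295), and Wfdc21 was 20.5 ± 4.52 against 4.55 ± 1.02 CPM (2.15, SE 0.24, adjusted p = 0.0426). In Tom+ cells Neto2 stood at 103 ± 17.0 against 4.45 ± 7.70 CPM, without passing (4.53, SE 1.95, adjusted p = 0.2025). Sufu (0.08) and Wfdc21 (-0.27) did not pass in Tom+ cells either. Between the fractions of TCL-1tg mice Neto2 did not pass (-0.45, adjusted p = 0.220), while Sufu (-1.16) and Wfdc21 (-4.67) were lower in Tom+ cells. Neto2 (ENSMUSG00000036902) lies on chromosome 8 at 85636588 to 85700924, Sufu (ENSMUSG00000025231) on chromosome 19 at 46396896 to 46488804 and Wfdc21 (ENSMUSG00000051748) on chromosome 11 at 83746940 to 83752642.

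No list had a member past the threshold over all genes. B-1 cell genes were nonetheless higher as a list (3 adjusted over the list alone, median 0.62, camera adjusted p = 1.97e-07, and adjusted p = 0.456 with an estimated correlation), with Ahnak at 290 ± 32.1 against 187 ± 42.7 CPM. Follicular genes were lower (median -0.29, camera adjusted p = 1.52e-08, and adjusted p = 0.411 with an estimated correlation), with Ighd at 2652 ± 1051 against 3773 ± 325 CPM. Immediate early and NF-kB genes were lower (6 adjusted over the list alone, median -0.29, camera adjusted p = 4.38e-08, and adjusted p = 0.328 with an estimated correlation), with Junb at 771 ± 171 against 1684 ± 813 CPM. B cell progenitor genes, at 1128 ± 301 against 788 ± 9.97 CPM, were higher (4 adjusted over the list alone, median 1.35, camera adjusted p = 7.32e-07, and adjusted p = 0.328 with an estimated correlation), with Cd24a at 640 ± 246 against 384 ± 2.55 CPM. Antigen presentation genes were lower (median -0.23, camera adjusted p = 1.21e-05, and adjusted p = 0.456 with an estimated correlation) and plasma cell genes higher (4 adjusted over the list alone, camera adjusted p = 0.000356, and adjusted p = 0.328 with an estimated correlation). The Tom- library of mouse 86 stood apart in B-1 and follicular genes, with Zbtb32 at 105 CPM (others 19.3 to 29.99), Bhlhe41 at 34.9 (9.77 to 11.2) and Ighd at 1077 (3110 to 3212). Without it the B-1 list had a median of 0.34 (camera adjusted p = 0.000468, and adjusted p = 0.428 with an estimated correlation) and the follicular list one of -0.22 (camera adjusted p = 9.16e-10, and 0.119 with an estimated correlation). Progenitor genes then had a median of 0.82 (camera adjusted p = 4.92e-05), and immediate early, antigen presentation and plasma cell genes kept their camera calls (1.62e-10, 9.34e-05 and 0.000468), though none of these 4 lists passed with an estimated correlation (adjusted p = 0.428 each). Cd5 was 5.08 ± 2.62 against 3.45 ± 1.85 CPM, Lef1 16.7 ± 6.75 against 11.4 ± 3.61 CPM and Bcl2 73.6 ± 7.89 against 109 ± 10.2 CPM, and none of them passed.

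NK cell markers were 46.7 ± 19.1 against 24.4 ± 3.13 CPM (3 higher adjusted over the list alone, camera adjusted p = 2.09e-06, and adjusted p = 0.328 with an estimated correlation) and monocyte markers 385 ± 181 against 280 ± 63.2 CPM (camera adjusted p = 0.00110, and adjusted p = 0.585 with an estimated correlation). T cell, erythroid, platelet and dendritic cell markers, at 683 ± 103 against 568 ± 91.8, 3958 ± 1587 against 2433 ± 2158, 80.9 ± 28.7 against 66.6 ± 10.4 and 297 ± 31.8 against 268 ± 13.9 CPM, gave camera adjusted p of 0.268, 0.160, 0.285 and 0.568. Neutrophil markers, too few for camera, stood at 6.20 ± 3.10 against 2.004 ± 0.836 CPM. Without the Tom- library of mouse 86 the monocyte list lost its call (0.0968), the NK cell list kept it (7.38e-05), and the T cell and erythroid lists gained one (0.00835 and 0.0203). With an estimated correlation none of these passed (adjusted p = 0.428 for NK cell and 0.648 for monocyte, T cell and erythroid markers). Without mouse 85 edgeR called 0 genes (1128 at an unadjusted p below 0.05, Neto2 adjusted p = 0.0663), and without mouse 83, 94, 95, 97 or 98 in turn it called 1. Without mouse 86 it called 5 higher and 7 lower, while DESeq2 called 174 and 83 and limma-voom 4 and 0 on all libraries.

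The difference between the Tom effects of TCL-1tg and WT mice asks whether the transgene alters the contrast between early-life and adult-life cells. Fcer2a fell further in TCL-1tg mice, from 947 ± 287 to 20.3 ± 18.0 CPM (n = 4) against 1738 ± 88.9 to 461 ± 314 CPM in WT mice (n = 3; difference of log2 fold changes -3.63, SE 1.02, adjusted p = 0.0453, and 0.129 with the mouse as a block), and so did Sell (-2.15, SE 0.59, 0.0418, and 0.129 with the block). Nid1 rose from 47.7 ± 30.6 to 727 ± 151 CPM in TCL-1tg mice, and was 42.1 ± 4.67 and 93.6 ± 30.7 CPM in WT mice (2.78, SE 0.53, 0.00690, and 0.0608 with the block). Igha was lower in Tom+ than in Tom- cells of TCL-1tg mice (39.6 ± 10.3 against 199 ± 161 CPM) and higher in WT mice (328 ± 171 against 26.6 ± 10.2 CPM; difference -5.95, SE 0.86, 0.00144, and 0.0434 with the block). In all, 1186 genes had a higher and 294 a lower Tom effect in TCL-1tg mice, and 8 and 5 of them remained with the block. Both fits shared 1 spread per gene between groups of unequal spread. Pearson correlations of log2(CPM + 1) between replicates were 0.856 to 0.898 in WT Tom+ and at least 0.969 in the other groups. Adjusted p of this comparison can therefore be too small, and limma-voom with quality weights called 13 higher and 70 lower. Fcer2a lost its call without mouse 83, 86, 94, 95 or 98 (adjusted p from 0.0712 to 0.125) and Sell without any mouse but 94 (0.0508 to 0.132), while Igha and Nid1 kept theirs. Of the genes named as passing in this comparison, only Igha, Zfp608, Oasl2, Zfp28, Mcoln3 and Dhx35 also passed with the block.

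Ribosomal protein genes had a lower Tom effect in TCL-1tg mice for 27 of 85 genes (64 adjusted over the list alone, median -1.15, camera adjusted p = 3.42e-38, and adjusted p = 0.377 with an estimated correlation), with Rps23 at -1.83, Rps29 at -2.42, Rps27 at -2.17 and Rps25 at -1.69 (adjusted p of 0.104, 0.117, 0.116 and 0.105 with the block). Oxidative phosphorylation genes followed with 12 of 82 lower (1 higher and 22 lower adjusted over the list alone, median -0.64, camera adjusted p = 8.52e-15, and adjusted p = 0.549 with an estimated correlation). The WT Tom+ libraries alone stood apart in the ribosomal share of counts (3.65%, other groups 1.42% to 1.61% on average) and in zeros (28.5%, others 4.35% to 6.50%). Follicular genes were lower (2 of 16, median -0.80, camera adjusted p = 0.000146, and adjusted p = 0.377 with an estimated correlation). So were constant regions (2 of 12, and 6 adjusted over the list alone, median -1.21, camera adjusted p = 6.43e-05, and adjusted p = 0.225 with an estimated correlation) and 63 of 257 Ig segments. Of 23 B-1 cell genes, 2 had a higher Tom effect, Nid1 and Itgam (0.0703 with the block; 3 adjusted over the list alone, camera adjusted p = 0.815). Of the other genes named for every comparison, Lef1 passed with levels at 1 count in WT Tom+ cells (0.0641 with the block).

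Type I interferon genes had a higher Tom effect for 7 of 27 (median 0.54, camera adjusted p = 0.00709, and adjusted p = 0.377 with an estimated correlation). Cell cycle genes did so for 5 of 31 (6 adjusted over the list alone, median 1.03, camera adjusted p = 0.0278, and adjusted p = 0.671 with an estimated correlation). Their leading members, Oasl2, Ifih1, Oasl1, Ifit1, Cenpe and Ccnb1, had 0 or 1 count in WT Tom+ cells, where 28.5% ± 2.82 of the tested genes were at 0. So had the 10 genes with the largest positive differences: Zfp28, Foxred2, Pard6g, Mcoln3, Pik3r6, Itgam, Fitm2, Nfil3, Gpt2 and Dhx35, which stood at 10.2 to 92.4 CPM in TCL-1tg Tom+ cells. B cell receptor genes Plcg2 (1.16, SE 0.22), Vav1 (0.65, SE 0.16) and Card11 (0.79, SE 0.21) and the homing gene Itgb7 (1.55, SE 0.33) had higher Tom effects without such zeros (adjusted p of 0.0641, 0.117, 0.102 and 0.0641 with the block). Leaving out a mouse took the calls of Vav1 (without mouse 85, 94, 95, 97 or 98, adjusted p from 0.0528 to 0.0941), Card11 (without any mouse but 86, 0.0507 to 0.123) and Itgb7 (without mouse 95, 0.0511). The largest negative differences, besides Igha and Fcer2a, were Tmem108 (-6.27), Tiam2 (-5.72), Zfp608 (-5.68), Ighg2b (-5.68), Trim36 (-5.55), Emid1 (-5.20), Ms4a4c (-4.21) and Anxa1 (-4.08), of which all but Zfp608 lost their calls with the block (adjusted p from 0.0641 to 0.163).

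camera called no marker list of other cells in this comparison (adjusted p of 0.439 for T cell, 0.107 for NK cell, 0.306 for monocyte, 0.520 for erythroid, 0.120 for platelet, 0.107 for dendritic cell and 0.142 for progenitor lists). With the mouse as a block B-1 associated V segments became called (adjusted p from 0.120 to 0.0414, and 0.671 with an estimated correlation and no block). Leaving out 1 mouse gave 671 to 1992 higher and 93 to 365 lower genes (671 and 93 without mouse 95, 732 and 99 without mouse 97, 104 lower without mouse 94, 112 lower without mouse 83, 1992 higher without mouse 98). limma-voom called 13 and 70, and genes of at least 20 CPM gave 61 and 119. The median difference of all genes was 0.27 with TMM, 0.24 with RLE and 0.11 with upper quartile scaling.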

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

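The test of cells of the Tom+ clone in the Tom- library of mouse 86 was chosen only after its values were seen. The splits with the mouse as a block and the test of sex on genes chosen without the mice measured were also added after seeing results. Of 64 tests of a measure within the TCL-1tg Tom+ or TCL-1tg Tom- group, 10 found a value far from the others by Dixon's test, where chance gives 1 in 20, or 3.2 tests. The WT groups (n = 3 each) were not screened, so a WT library that stands apart is not flagged here.

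More genes were higher than lower in TCL-1tg Tom+ relative to WT Tom+ cells, 737 against 122. Of the genes called with a mean of at least 50 CPM 64.0% were higher (105 higher, 59 lower) and of those of at least 20 CPM 58.1% (129 and 93), against 608 higher and 29 lower below 20 CPM, and a test of only the genes of at least 20 CPM called 10 higher and 11 lower. Low complexity of the WT Tom+ libraries may therefore account for part or all of the excess, and its share cannot be told apart from a transgene effect by these values. Sex as the whole cause is argued against, since over genes chosen from the Xist-expressing mice and 2 WT mice the difference from the third WT mouse was 82.9% to 88.8% as large in the mice without Xist as in those with it (101% over the genes called higher, which were chosen with all 4 mice and decide nothing). Whether the transgene itself raises these genes stays open as untested.

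Ribosomal protein genes were lower in TCL-1tg Tom+ than in WT Tom+ cells, with a median of -1.22 over the 80 genes of at least 20 CPM. A trend with exonic length is argued against, since 92.2% of the median was left after it was subtracted (-1.12). That length joins all annotated exons of a gene (median 1805.5 bases in ribosomal protein genes, 4713 in the others). It can exceed the length of the transcript itself, so a bias for very short transcripts cannot be decided. A trend of other genes of like exonic length and abundance is argued against, since 0 of 10000 matched random lists had a median as low. That is 0.01%, the smallest share they can give (lowest list -0.32, central 95% of lists -0.20 to 0.08). The lists were drawn gene by gene, so they do not show how low a set of genes that move together would go. The WT Tom+ libraries alone departed from the other groups, in the ribosomal share (3.65% against 1.42% to 1.61%) together with zeros (28.5% against 4.35% to 6.50%), so a technical property of these libraries stays open, as does a difference in growth state, both untested.

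The Tom- library of mouse 86 stood apart from the other TCL-1tg Tom- libraries in B-1 genes, with Zbtb32 at 105 CPM (others 19.3 to 29.99) and Bhlhe41 at 34.9 (9.77 to 11.2), and in follicular genes, with Ighd at 1077 (3110 to 3212) and Sell at 1112 (1730 to 1763). Cells of the dominant Tom+ clone of that mouse in its Tom- sort are argued against. Its B-1 genes would need a mixing fraction of 7.80% (median of 20 genes), yet Ighv12-3 took 0.311% of Ighv counts where 10.5% was predicted, 0.964% of the predicted excess. The light chains of this library were skewed as well. Iglv1 took 22.8% of light-chain V counts (other TCL-1tg Tom- libraries 10.9% to 13.3%), and lambda 43.8% of light-chain constant counts (28.8% to 33.8%). Its effective number of light-chain segments was 36.8 (49.4 to 51.8), while that of Ighv segments was 67.4 (63.0 to 66.4). Unmarked B-1 cells that use other V segments might be present, and this was not tested.

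Further values set apart from the other TCL-1tg Tom+ libraries were the share of the leading Ighv segment in mouse 97 (34.2%, others 93.6% to 96.5%) and its effective number of Ighv segments (5.65, others 1.25 to 1.46). The sum of erythroid markers was far above the others in mouse 95 (6330 CPM, others 1277 to 2081), and the lambda share of light-chain constant counts in mouse 94 (83.7%, others 16.6% to 27.2%), where Iglv2 led. Spn (23.1 CPM, others 41.9 to 43.1) and Ctla4 (31.2 CPM, others 118 to 127) were far below the others in mouse 86.

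The Tom effect differed between genotypes for 1186 genes with a higher and 294 with a lower effect in TCL-1tg mice, a difference between groups. Among the genes named for every comparison this held for Fcer2a (-3.63), Sell (-2.15) and Lef1 (9.96, with 1 count in WT Tom+ cells). With the mouse as a block 8 and 5 genes were called, none of these 3 among them. Both fits shared 1 spread per gene between groups of unequal spread.

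Other splits of the same libraries tested how often a random split gives as many calls, as a check on chance. For TCL-1tg against WT in Tom+ cells the real grouping gave 859 calls and the highest other split 0 (1 of 35 splits reached the real count). For the difference of Tom effects the real grouping gave 1480 and the highest other split 1 (1 of 35 splits) without a block. With the mouse as a block the difference had 13 calls and the highest other split 0 (1 of 35 splits). Chance is argued against for these counts, though 1 of 35 is the smallest share such splits allow and is not adjusted over the comparisons. The splits cannot tell the genotype from the low complexity that the WT Tom+ libraries share. For TCL-1tg against WT in Tom- cells the real grouping gave 3 and the highest other split 3 (2 of 35 splits), so chance cannot be excluded for this count. The splits compare counts of calls and do not judge single genes such as Neto2. For Tom+ against Tom- there are too few splits that part every pair (1 of 8 reached the real count in TCL-1tg mice and 1 of 4 in WT mice).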

How the results depend on the processing

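The alternatives chosen only after seeing results were a minimum mean of 20 CPM, leaving out the Xist-expressing mice 94 and 95, and leaving out the Tom- library of mouse 86. No gene called in a comparison was called in the other direction under any alternative. Counts are given as higher and lower genes. Fewer genes or mice is named where a setting removed them, and the cause of a change was not tested.

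For Tom+ against Tom- in TCL-1tg mice (1541 and 1342), upper quartile scaling gave 1350 and 1540, limma-voom called 2185 lower, the fit of all 14 libraries 646 and 715, the 20 CPM minimum (fewer genes) 947 and 796, and leaving out the Xist-expressing mice (fewer mice) 166 and 165. Leaving out 1 mouse gave 665 to 1472 higher and 595 to 1105 lower. In WT mice (67 and 21), upper quartile scaling gave 104 higher, DESeq2 1537 and 2610, limma-voom 391 and 773, no filter 131 and 58, and the strict filter 309 and 116. The mouse as a block gave 0 and 0, the fit of all libraries 1116 and 2721, the 20 CPM minimum 385 and 83, and leaving out 1 mouse 0 to 0 higher and 0 to 0 lower.

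For TCL-1tg against WT in Tom+ cells (737 and 122), upper quartile scaling gave 486 higher, DESeq2 2466 and 1201, no filter 62 and 27, and the strict filter 19 and 8. The fit of all libraries gave 2700 and 1134, the 20 CPM minimum 10 and 11, leaving out the Xist-expressing mice 0 and 0, and leaving out 1 mouse 0 to 1413 higher and 0 to 266 lower. In Tom- cells (3 and 0), DESeq2 gave 174 and 83, no filter 13 and 9, the strict filter 5 higher, the fit of all libraries 0, leaving out the Xist-expressing mice 1, leaving out the Tom- library of mouse 86 5 and 7, and leaving out 1 mouse 0 to 5 higher and 0 to 7 lower. For the difference of Tom effects (1186 and 294), DESeq2 gave 1929 and 988, limma-voom 13 and 70, no filter 108 lower, the strict filter 247 higher, and Ig genes removed 175 lower. The block gave 8 and 5, the 20 CPM minimum 61 and 119, leaving out the Xist-expressing mice 1 and 1, and leaving out 1 mouse 671 to 1992 higher and 93 to 365 lower.

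With an estimated correlation camera called 1, 0, 0, 0 and 0 lists in the order above, and fry called 29, 30, 28 and 26 lists in the mixed test of the first 3 comparisons and the last, and 11 and 0 lists in 1 direction for the genotypes in Tom+ and Tom- cells. Leaving out the Tom- library of mouse 86 reversed the ribosomal protein list between genotypes in Tom- cells, downward before and upward after (camera adjusted p = 0.868), and the cause was not tested. The difference of Tom effects for Mki67 (-0.93) ran from -1.90 to 6.52 when 1 mouse was left out, and it reversed without mouse 85 (6.52). That mouse held nearly all Mki67 of WT Tom+ cells (32.0 CPM, against 0.123 in mouse 83 and 0 in mouse 98). The rise of the immunoglobulin share in Tom+ cells (0.860 points) ran from 0.580 to 1.07 and lost its exact p below 0.05 in 6 of these fits (0.859, 0.864, 0.835, 0.580, 0.927 and 0.882), each of which kept mouse 97, where the share was lower in Tom+ cells (2.69% against 3.11%). The share in TCL-1tg minus WT Tom+ cells (0.462) ran from -0.0976 to 0.895. Beyond the list calls named in the report and the other observations, the block changed no other list call of Tom+ against Tom-. Low depth and complexity of the WT Tom+ libraries limit every comparison that uses them.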

Other observations

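Leaving out the Tom- library of mouse 86 was chosen only after seeing results. The lists below were fixed with the others and are those not described so far. In TCL-1tg mice Cd80, a costimulatory ligand among the memory B cell genes, rose in Tom+ against Tom- cells, at 64.9 ± 6.99 against 4.07 ± 3.40 CPM (n = 4). Of 16 memory genes, 7 were higher and 3 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.000239, and adjusted p = 0.0885 with an estimated correlation). Nt5e, which encodes the ectoenzyme CD73, rose by 3.83 (SE 0.37) and Cd44 by 1.82 (SE 0.23). Of 18 plasma cell genes, 5 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00364, and adjusted p = 0.492 with an estimated correlation). Prdm1 was 63.1 ± 10.5 against 7.23 ± 2.33 CPM, while Sdc1, the plasma cell surface marker CD138, fell by 3.50 (SE 0.48). Of 27 type I interferon genes, 7 were lower and 0 higher (10 adjusted over the list alone, median -0.67, camera adjusted p = 0.00701, and adjusted p = 0.376 with an estimated correlation), among them Rtp4 (-4.45, SE 0.71), Stat2 (-1.02, SE 0.21, adjusted p = 0.0669 without mouse 94 and 0.0780 without mouse 95) and Irf7 (-1.05, SE 0.23, 0.0699 without mouse 97). Of 18 B lineage identity genes, 6 were lower and 1 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.0110, and adjusted p = 0.692 with an estimated correlation), with Cd72 (-2.82, SE 0.28) and Ebf1 (-0.93, SE 0.13) lower and Blk (0.89, SE 0.10) higher.

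Other lists of the same comparison went both ways. Of 15 marginal zone genes, 5 were higher, such as Cd9 and S1pr3, and 3 lower, such as Cr2 (camera adjusted p = 0.102, 0.0120 with the mouse as a block, and adjusted p = 0.692 with an estimated correlation and no block). Homing genes split into 5 higher, among them Itgb1 (2.60, SE 0.28), and 7 lower, among them Sell (6 and 9 of 20 adjusted over the list alone, camera adjusted p = 0.864). Apoptosis regulators had 5 of 23 higher, among them the BH3-only genes Bid (1.32, SE 0.17) and Bbc3 (2.68, SE 0.43), and 4 lower (7 and 5 adjusted over the list alone, camera adjusted p = 0.328). Toll-like receptor and innate sensing genes had 4 of 20 higher and 4 lower, with Irf8 at -2.06 (SE 0.25) and Tlr1 at -1.21 (SE 0.12; camera adjusted p = 0.724). B cell receptor genes had 1 of 22 higher, Bcl10, and 4 lower (camera adjusted p = 0.0770), and immediate early genes 7 of 28 higher and 3 lower, with Fos at 1.86 (SE 0.26) and Dusp2 at -2.36 (SE 0.12; camera adjusted p = 0.763).

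Metabolic lists were not called there: glycolysis genes (5 of 20 higher, 2 lower, camera adjusted p = 0.193) with Tpi1 at 1.36 (SE 0.20), and cholesterol and fatty acid genes (3 of 21 higher, 1 lower, 0.636) with Cyp51 at 1.78 (SE 0.19). Antigen presentation genes (3 of 19 higher, 2 lower, 0.801) included Cd86 at 1.29 (SE 0.23) and Cd40 at -1.33 (SE 0.14). Of the 5 fetal and neonatal regulators, Arid3a was higher (1.52, SE 0.34) and Igf2bp3 lower (-2.73, SE 0.64; camera adjusted p = 0.883). Arid3a lost its call without mouse 94, 95 or 97 (adjusted p of 0.0654, 0.0572 and 0.0625) and Igf2bp3 without mouse 86 or 95 (0.0802 and 0.119). Epigenetic regulators had 2 of 20 higher and 3 lower (0.864), with Tet1 at -3.74, called no longer without mouse 86, 95 or 97 (adjusted p of 0.0790, 0.128 and 0.0706) or with the mouse as a block (0.0503). Ribosomal protein genes had 2 of 85 higher and 0 lower (median 0.26, camera adjusted p = 0.0391, 0.0971 with the mouse as a block, and adjusted p = 0.934 with an estimated correlation), oxidative phosphorylation genes 2 of 82 higher and 2 lower (0.0770) and mitochondrially encoded genes 0 of 23 (0.753).

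In WT mice, memory genes (2 of 16 higher, camera adjusted p = 0.0188, and adjusted p = 0.173 with an estimated correlation) and plasma cell genes (1 of 18 higher, 0.00255, and adjusted p = 0.173 with an estimated correlation) were higher as lists in Tom+ cells. Ribosome biogenesis genes had 0 of 22 past the threshold and 6 higher adjusted over the list alone (camera adjusted p = 5.08e-07, and adjusted p = 0.173 with an estimated correlation), and mitochondrially encoded genes 0 of 23 (median 0.62, camera adjusted p = 4.86e-05, and adjusted p = 0.173 with an estimated correlation). Lower as lists were B cell receptor genes (1 of 22, Vav1, 11 adjusted over the list alone, 0.00546, and adjusted p = 0.173 with an estimated correlation). So were cell cycle genes (0 of 31, 6 adjusted over the list alone, 0.00546, and adjusted p = 0.173 with an estimated correlation) and interferon genes (0 of 27, 8 adjusted over the list alone, 0.00991, and adjusted p = 0.265 with an estimated correlation). Genes lost to 0 in the WT Tom+ libraries, where 28.5% ± 2.82 of the tested genes were at 0, cannot be told apart from lower expression of these lists. Immunoglobulin constant regions were higher as a list (median 0.53, 0.00165, and adjusted p = 0.229 with an estimated correlation).

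Between genotypes camera called further lists. In Tom+ cells antigen presentation genes (0 of 19 higher, 1 lower, median -0.19, camera adjusted p = 0.0314, and adjusted p = 0.694 with an estimated correlation) and mitochondrially encoded genes (0 of 23, -0.22, 0.00611, and 0.694) were lower in TCL-1tg mice as lists. In Tom- cells no member of the following lists passed. Interferon genes (27 genes, median 0.25, 0.00105, and 0.585), B lineage genes (18 genes, 0.09, 0.0187, and 0.657) and oxidative phosphorylation genes (82 genes, 0.09, 0.0208, and 0.714) were higher as lists, and ribosomal protein genes (85 genes, -0.09, 0.00307, and 0.769) lower. Without the Tom- library of mouse 86 the B lineage list (0.303) and the ribosomal list (0.868, upward) lost their calls, and the mitochondrially encoded list gained one (0.0179, upward, and 0.602 with an estimated correlation). The Tom effect was lower in TCL-1tg mice for the B lineage list (0 of 18, median -0.14, 0.0480, and 0.671) and the mitochondrially encoded list (0 of 23, -0.47, 0.00275, and 0.671).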
